A study of Capra hircus with 2 samples.

How the data were processed

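Small RNA from goat mammary gland was sequenced in 2 libraries, 1 for early lactation and 1 for early involution. Per the labels, each library was made from an equal mixture of RNA from 5 goats of the same stage. The extract protocol in the labels names selection of RNA of 18 to 30 nt, ligation of a 5' and a 3' adaptor, reverse transcription with PCR, and Solexa sequencing.

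The deposited files hold raw counts: each distinct clean tag is listed with its length and the number of reads that carried it. Per the description deposited with the files, the authors removed low-quality reads, trimmed the 3' adaptor, discarded 5' adaptor contaminants, tags under 18 nt and polyA tags, and collapsed identical reads. Tool versions and any mapping step are not given in the sources used here. That description gives a range of 18 to 30 nt, whereas the tags reached 44 nt in both libraries. Filtering logs deposited by the authors give the read count at each step. Each log was tied to a library only because its number of clean reads equalled the total of that library, which held for both. PCR copies were not marked by molecular identifiers, so every interval given here covers counting error only.

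No goat genome sequence was used here. Mature miRNAs were recognised by sequence, with a panel of 168 conserved vertebrate mature miRNA sequences that was written from general knowledge before the data were examined. The names are those of the conserved vertebrate miRNAs, not of a goat miRNA catalogue, and a goat sequence that departs from the panel is missed. Of the 168 names, 139 matched a gene symbol in the RefSeq gene table of goat assembly ARS1.2, which lists 264 miRNA genes. That table served for names and for gene neighbourhood. The files name no genome build, so coordinates are not given.

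A tag was assigned to a miRNA when it had at least 18 nt, began at the first base of the mature sequence, matched it without mismatch over the shorter of the pair, and was at most 3 bases longer. Tags that fitted more than 1 miRNA were set aside, which took 0.0339% of tags in lactation and 0.0641% in involution. Counts were divided by all clean tags of the library and given as tags per 1000000 clean tags (TPM, where T stands for tags). Intervals are 95% intervals: exact Poisson for a level, exact Clopper-Pearson for a share, and conditional Clopper-Pearson for the ratio of involution to lactation. A count of 0 allows up to 3 counts, equal to 0.166 TPM in lactation and 0.406 in involution.

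With 1 library per group no test between the stages was possible and no p-value was computed. A miRNA was counted as higher or lower in involution when its ratio was at least 2 or at most 0.5, its whole interval lay beyond 1, and it reached 10 TPM in at least 1 library. Fixed lists of miRNAs, 20 in number, cover seed families, genomic clusters and markers of cell types (epithelial, leukocyte, stromal, endothelial, erythroid, muscle and liver). The median log2 ratio of a list is given with its percentile among 10000 random lists of the same size matched on mean level in 10 bins, as a description of these libraries. Named miRNAs are the 10 with the most TPM over both libraries, the 10 with the highest and the 10 with the lowest ratios among those that reached 100 TPM in a library with an interval beyond 1, and up to 4 of the most abundant members of each list. Outside this rule miR-205, miR-222, miR-30c, miR-23b, miR-494, miR-142-5p, miR-342, let-7e and miR-22-3p were named after their values had been seen. The panel, lists, rules and most alternatives were fixed before the data were examined.

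Length variants were measured for miRNAs with at least 1000 tags in both libraries: tags shorter or longer than the panel sequence at the 3' end, and tags that lacked 1 to 6 bases at the 5' end. Pairs of miRNAs from opposite arms of a precursor, or from genes within 10 kb of each other, were compared after the ratios had been seen. Tags without any 14-base match to the panel were summarised by sequence and left unnamed.

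Alternatives covered scaling (miRNA-assigned tags, median-of-ratios, edgeR TMM, totals without the most abundant miRNA), assignment (identical tags, shifted start, 1 mismatch outside the first 8 bases, shared tags split equally), the filter on level, and thinning of the deeper library. Another 3 were added after the data had been seen: assignment by the first 18 bases, use of tags of 18 to 30 nt alone, and removal of a linear trend with GC content. The procedure was tested on simulated counts for 165 miRNAs with the totals of these libraries. Of the intervals, 95.7% held the simulated ratio. All simulated 4-fold differences were called in each direction, and 0% of the 1.5-fold or unchanged miRNAs were. The simulated counts varied by counting error alone. These shares therefore say nothing of false calls from spread between animals or library preparations. Calculations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, R 4.3.3 with edgeR 4.0.16 for TMM factors, and matplotlib 3.10.9.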

Results

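The mammary gland of the dairy goat was sampled at opposite ends of its secretory cycle. The lactation library represents the gland on day 10 after parturition. The involution library represents day 5 after forced weaning at late lactation, day 218 after parturition, when milk removal has stopped and the secretory tissue regresses. The lactation library held 18031615 clean tags of 305711 distinct sequences, and the involution library 7385833 clean tags of 259250 sequences, so lactation was 2.44 times deeper. There was 1 pooled library per stage and therefore no replicate, and the spread between animals is unknown. No library represents late lactation before weaning. A difference between the libraries can therefore reflect weaning or the time since parturition, day 10 against day 218, and these cannot be told apart.

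Both libraries were made up mainly of miRNA-sized tags. The commonest length was 22 nt, at 44.4% of tags in lactation (95% interval 44.38 to 44.43%) and 35.7% in involution (35.64 to 35.71%). Tags of 20 nt took 18.2% in lactation and 25.2% in involution. Tags of 20 to 24 nt together made up 91.2% and 88.9%. Panel miRNAs took 80.8% of the tags in lactation and 74.3% in involution, and 165 of the 168 panel miRNAs had at least 1 tag, the exceptions being miR-135b, miR-489 and miR-34b. The libraries also differed outside the miRNAs: 14.03% of high-quality involution reads had been removed as 5' adaptor contaminants, against 0.0505% in lactation, and tags made of 2 joined miRNAs numbered 4167 in lactation and 74 in involution, or 231 and 10.02 per 1000000 clean tags.

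**Figure D1:**
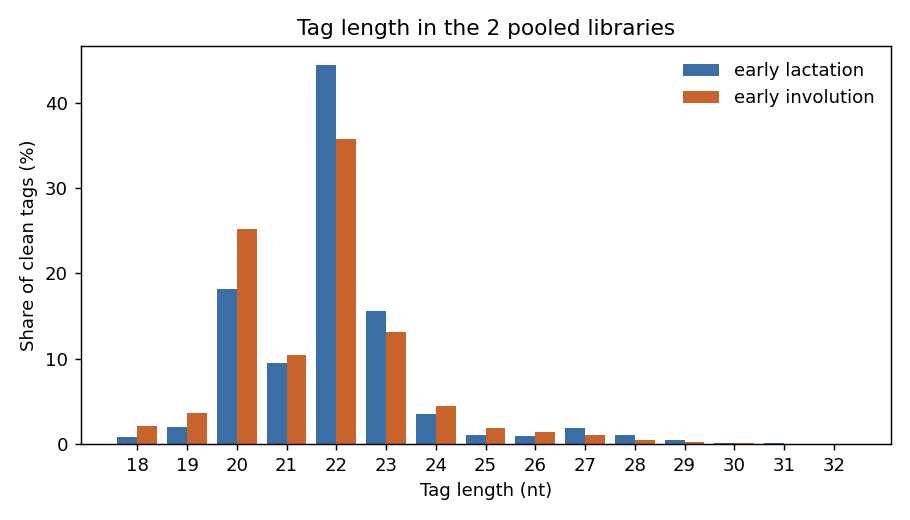
Share of clean tags (%) by tag length (nt), up to 32 nt, in the early lactation library (blue bars) and the early involution library (orange bars), 1 pooled library each. The peak at 22 nt reached 44.4% in lactation and 35.7% in involution, while the 20 nt share was 18.2% against 25.2%.

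The main question of the design is which miRNAs differ between the lactating and the involuting gland. The miR-29 family, known to target collagen and other matrix mRNAs, was higher in involution, with miR-29b at 56.7 times (50.9 to 63.3) and miR-29c at 44.1 times (40.99 to 47.6) its lactation level. The epithelial and endocrine miRNA miR-375 was 25.1 times higher (24.2 to 26.0). On the other side, miR-148a, an abundant miRNA of lactating gland and milk, was 2.27-fold lower in involution (2.26 to 2.28), and its relative miR-148b was 2.94-fold lower (2.84 to 3.05). The single most abundant miRNA, miR-143, differed by 1.03 times (1.026 to 1.030) between the libraries. These sizes hold for scaling to all clean tags. With median-of-ratios and TMM factors miR-29b was 32.2 and 33.6 times higher, and miR-375 14.3 and 14.9 times. Under the same factors miR-148a was 3.996-fold and 3.84-fold lower, and miR-143 1.71-fold and 1.64-fold lower.

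Levels are given as tags per 1000000 clean tags (TPM). Of 143 miRNAs that reached 10 TPM, 64 were at least 2-fold higher in involution, 9 were at least 2-fold lower and 70 lay between. The median log2 ratio of all 143 was 0.81, or 1.76-fold. The split depended on the scaling: with median-of-ratios factors, which moved the median by -0.81 on the log2 scale, 45 miRNAs were higher and 36 lower, and with TMM factors, which moved it by -0.76, 47 were higher and 34 lower. All 9 miRNAs called lower under the main scaling were also called lower under both of these, which follows from factors that lower every ratio alike. Counting identical tags alone moved the ratio of 15 of the 74 miRNAs named by rule by more than 1.5 times. It was larger for 13, among them miR-29c at 96.9, miR-15a at 29.97, miR-451 at 10.96, miR-424 at 9.58, miR-29a at 8.94, miR-99a at 7.67, miR-142-3p at 4.39 and miR-141 at 4.29, and smaller for miR-144 at 16.97 and miR-16.

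**Figure D2:**
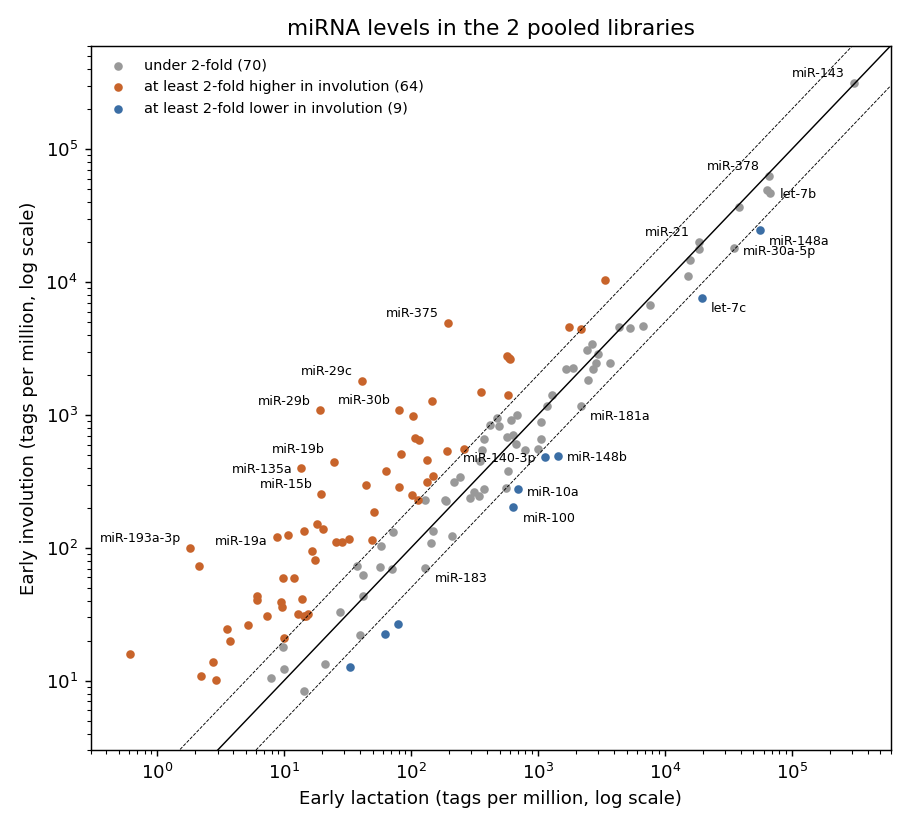
Level of each of 143 miRNAs in early lactation (x axis) and early involution (y axis), in TPM on log scales; the solid line marks equal levels, the dashed lines a 2-fold difference, and some of the miRNAs named in the text are labelled. The 64 miRNAs at least 2-fold higher in involution (orange) include miR-29b, miR-29c and miR-375 far above the line, and the 9 at least 2-fold lower (blue) include miR-148a and let-7c.

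A few miRNAs made up most of each library. The 10 most abundant took 85.4% of the miRNA tags in lactation and 82.1% in involution, and miR-143, a miRNA of smooth muscle and stromal cells, alone took 38.3% and 42.8%. Its level was 309541 TPM in lactation and 318197 in involution, for the panel sequence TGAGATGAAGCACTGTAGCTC and its end variants. Next came miR-378 at 66176 and 63269 TPM, let-7b at 67949 and 47001, let-7a at 63814 and 49507, and let-7f at 38394 and 36763. The level of miR-148a (TCAGTGCACTACAGAACTTTGT) was 55907 TPM in lactation and 24602 in involution. That of miR-30a-5p was 35129 and 18053, or 1.95-fold lower (1.93 to 1.96), just short of the 2-fold limit, but 1.197-fold lower with identical tags alone. The remaining 3 were within 1.1-fold of equality under the main scaling: miR-146b at 18617 and 17924 TPM, miR-21, a miRNA induced in many injured tissues, at 18582 and 20202, and miR-103 at 15904 and 14739.

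The 10 highest ratios among well-measured miRNAs began with miR-29b (TAGCACCATTTGAAATCAGTGTT), at 19.1 TPM in lactation and 1085 in involution. The ratio of miR-193a-3p was 54.8 (38.7 to 80.2), but it rested on 33 tags in lactation against 741 in involution. The level of miR-29c (TAGCACCATTTGAAATCGGTTA) went from 41.1 TPM in lactation to 1814 in involution, and that of miR-375 (TTTGTTCGTTCGGCTCGCGTGA) from 197 to 4941. The ratio of miR-135a was 29.1 (25.6 to 33.3). The others were miR-19b at 17.9 times, miR-19a at 13.6, miR-30b at 13.5, miR-15b at 13.0 and miR-214 at 11.6. All 10 stayed at least 2-fold higher under median-of-ratios and TMM scaling.

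On the lower side the ratios were more moderate. The level of miR-100 was 642 TPM in lactation and 202 in involution, 3.18-fold lower (3.01 to 3.36), although its log2 ratio of -1.67 became -0.63 when only tags identical to the panel sequence were counted. The let-7 member let-7c was 2.57-fold lower (2.55 to 2.60), miR-10a 2.53-fold (2.42 to 2.66) and miR-140-3p 2.34-fold (2.26 to 2.42). The 10 lowest ratios were completed, beside miR-148a and miR-148b, by 4 miRNAs that did not reach 2-fold: miR-99b at 1.98-fold lower, miR-30a-5p at 1.95, miR-181a at 1.87 and miR-183 at 1.83.

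Seed families differed in how their members moved. All 3 members of the miR-29 family were higher in involution, with a median log2 ratio of 5.46 at percentile 99.5 of the random lists, and miR-29a, the most abundant in both stages, was 4.82 times higher (4.71 to 4.94). The miR-148 family stood at the other end, with a median of -1.18 at percentile 1.33. Its members miR-148a and miR-148b were called lower, and miR-152 was 1.61-fold lower (1.56 to 1.67) without reaching the limit, which it passed with median-of-ratios and TMM factors. In the miR-181 family, best known from lymphocyte development, the median was -0.84 at percentile 2.49, with miR-181a and miR-181b both under 2-fold lower with scaling to all tags and over 2-fold lower with those factors. Median-of-ratios and TMM factors shift all ratios alike, so they change a percentile only through the level bins. Some of 20 lists can fall outside the 2.5 to 97.5 percentile range at random, and 3 did, the miR-29, miR-148 and miR-181 families. Of them the miR-29 family stayed outside it in the 11 alternatives that gave values for lists; the miR-148 family moved to percentile 3.88 with median-of-ratios or TMM factors, and the miR-181 family to as far as 5.99 when only identical tags were counted.

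In the let-7 family, which represses growth-promoting mRNAs in differentiated cells, 1 of 9 members was lower and 8 were not called. Its median log2 ratio was -0.06 at percentile 42.3, a sign that flipped to 0.06 when tags were scaled to miRNA tags. With median-of-ratios factors the median was -0.88, and with TMM factors -0.82, and 4 of the 9 were then lower: let-7a, let-7b, let-7c and let-7e. With identical tags alone the let-7 median was -0.21, with 2 of the 9 higher, 1 lower and 6 not called. The miR-30 family was mixed: miR-30b was 13.5 times and miR-30c 6.10 times higher, whereas the more abundant miR-30a-5p, miR-30d and miR-30e-5p had log2 ratios of -0.96, -0.17 and -0.29. Its median of -0.17, at percentile 30.8, became 0.71 with identical tags alone and -0.99 and -0.93 with median-of-ratios and TMM factors, where miR-30a-5p and miR-30e-5p were over 2-fold lower. Counted by identical tags alone, miR-30e-5p was instead 1.63 times higher (1.55 to 1.71).

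The miR-15/16 family, which represses cyclin mRNAs, had 3 of 4 members higher and a median log2 ratio of 2.68 at percentile 94.8, with miR-15a at 5.98 times (29.97 with identical tags alone, on 51 lactation tags), miR-15b at 13.0 and miR-497 at 6.89. The fourth, miR-16, was 1.78 times higher on 2331 lactation tags, but the panel sequence missed most of its tags: by the first 18 bases alone it had 66059 lactation tags and a ratio of 1.38 (1.36 to 1.39). With identical tags alone miR-16 was 8.92-fold lower, on 283 lactation and 13 involution tags. The first 18 bases gave 66059 and 37250, so the identical tags were few and do not set its direction. Under the main rule with median-of-ratios and TMM factors its ratio was 1.01 and 1.05. In the miR-17-92 and paralogous clusters, known for promoting proliferation, 6 of 9 members were higher, among them miR-20a at 2.74 times, which fell short of 2-fold under median-of-ratios and TMM scaling. With those scalings 4 and 5 of the 9 were higher. The clusters' median was 1.78 at percentile 89.2 under the main scaling, and miR-92a, miR-25 and miR-93 were not called, miR-25 just short of 2-fold and the other two at log2 ratios of 0.57 and 0.26. The miR-23/24/27 clusters had 3 of 5 members higher and a median of 1.28 at percentile 83.8, with miR-23a at 9.48 times, miR-23b at 6.28 and miR-27a at 2.43, the last under 2-fold with either of those scalings, while miR-24 and miR-27b were not called. With median-of-ratios factors miR-24 was 2.07-fold lower. With identical tags alone 2 of the 5 were higher, at a median of 0.70 and percentile 77.1. The first-18-base rule left 1 member of the miR-23/24/27 clusters, at -0.21.

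Other families and clusters held members on both sides. In the miR-99/100 and miR-125 families miR-99a was 2.12 times higher, with log2 ratios of 0.27 and 0.33 under median-of-ratios and TMM factors and 2.94 with identical tags alone, miR-100 was lower, and miR-125b and miR-99b were not called, at log2 ratios of 0.99 and -0.98, although miR-99b was over 2-fold lower with those factors; the median was 0.30 at percentile 28.1. In the miR-424 cluster miR-424 was 3.53 times higher and miR-542-3p 2.97-fold lower, for a median of 0.12 at percentile 16.2. In the miR-34 family, effectors of the p53 response, miR-34a was 3.77 times higher and miR-34c 2.64-fold lower, for a median of 0.26 at percentile 11.7. The DLK1-DIO3 locus, an imprinted miRNA cluster, had 1 of 7 members higher, miR-494 at 5.28 times, and a median of 0.25 at percentile 4.46; miR-379, miR-127, miR-411 and miR-432 were not called. With median-of-ratios factors 3 of the 7 were lower, miR-379, miR-127 and miR-432, and with TMM factors 2, while with identical tags alone none of the 5 that could be tested was called. The direction of miR-127 turned there, to a ratio of 1.37 (1.23 to 1.53) from 0.69 under the main rule. The medians of all 4 of these groups turned negative under median-of-ratios and TMM scaling.

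**Figure D3:**
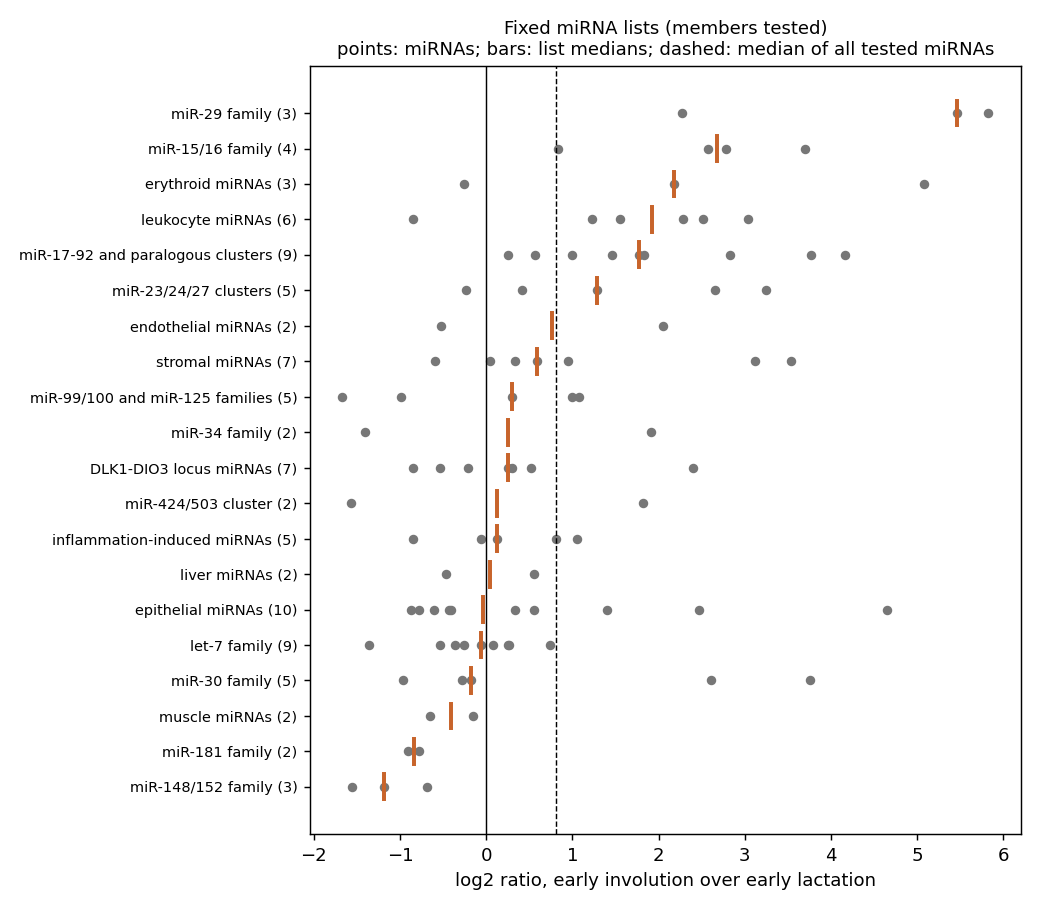
Log2 ratio of involution over lactation for the tested members of each fixed list (grey points), with the list median (orange bar), a solid line at 0 and a dashed line at the median of all 143 tested miRNAs, 0.81; numbers in brackets are members tested. The miR-29 family lies at 5.46 and the miR-148 family at -1.18 with scaling to all tags, and medians between 0 and 0.76 turn negative under median-of-ratios and TMM scaling.

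Marker lists of cell types did not move as blocks. Among epithelial miRNAs 3 of 10 were higher, miR-375, miR-141 at 2.64 times and miR-205 at 5.55 times, and 7 were not called, among them the abundant miR-200c at 15162 TPM in lactation and 11203 in involution and miR-200b at 2456 and 3095. Their median log2 ratio was -0.04 at percentile 19.9, and it became 0.09 when scaled to miRNA tags, -0.85 with median-of-ratios and -0.79 with TMM factors. With either of these factors 2 of the 10 were higher and 5 lower; miR-141 was under 2-fold, and miR-200c was 2.38-fold and 2.28-fold lower. Of 6 leukocyte miRNAs 5 were higher, with a median of 1.92 at percentile 78.0: miR-223, a granulocyte miRNA, was 8.19 times higher (7.23 to 9.28), miR-150 of mature lymphocytes 5.71 times, miR-142-5p 2.95 times, miR-342 4.88 times and miR-142-3p 2.35 times. With those factors 3 of the 6 were higher, as miR-142-3p and miR-142-5p were under 2-fold, and miR-155 was over 2-fold lower. The most abundant of them, miR-155, had a log2 ratio of -0.85 under the main scaling, so that the summed level of the list was nearly equal, at 1184 TPM in lactation and 1165 in involution. Counted by identical tags alone, miR-155 had a log2 ratio of -0.15. By the first 18 bases miR-342 had 11.05 times its lactation level, on 311 and 1407 tags, where the main rule kept 40 and 80.

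Of the erythroid miRNAs, miR-451 was 4.53 times higher (4.43 to 4.64) and miR-144 33.9 times (24.5 to 48.2), while miR-486 had a log2 ratio of -0.25; the median was 2.18 at percentile 84.5, and 3.45 at percentile 97.9 with identical tags alone. Among stromal miRNAs miR-145 was 8.70 times and miR-214 11.6 times higher and 5 were not called, including miR-143, miR-10b and miR-199a-3p. The stromal median of 0.59, at percentile 67.1, turned to -0.23 with median-of-ratios and -0.17 with TMM factors. Of the endothelial pair miR-126-5p was 4.15 times higher and miR-126-3p had a log2 ratio of -0.52, for a median of 0.77 at percentile 56.1 that became -0.05 with median-of-ratios factors. Inflammation-induced miRNAs had 1 of 5 members higher, miR-222 at 2.07 times, or 1.18 and 1.23 times with median-of-ratios and TMM factors, and miR-21, miR-146b, miR-155 and miR-221 were not called; the median was 0.12 at percentile 45.2 and negative under both of those scalings. With either of these factors miR-486, miR-10b and miR-126-3p were over 2-fold lower. Muscle miRNAs had a median of -0.40 at percentile 4.47, or 2.465 with the GC trend removed, with neither miR-1 nor miR-206 called; with median-of-ratios and TMM factors the median was -1.22 and -1.16 and miR-206 was 2.77-fold and 2.66-fold lower. The rule kept 35.8% of the miR-1 tags that its first 18 bases gave in lactation. The liver list held miR-192 and miR-194, neither called, at a median of 0.04, percentile 23.4, which was -0.77 and -0.71 under those scalings, where miR-192 was 2.44-fold and 2.34-fold lower.

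Mature miRNAs made from a shared precursor or from neighbouring genes often differed in ratio. Of 35 such pairs, 7 of opposite arms and 28 of neighbours within 10 kb, 32 had ratios whose counting intervals lay apart and 17 were more than 2-fold apart. Some miRNAs, such as miR-19b and miR-20a, occur in several pairs, so the pairs are not independent. The neighbours miR-143 and miR-145 had log2 ratios of 0.04 and 3.12, miR-30d and miR-30b -0.17 and 3.76, miR-92a and miR-19b 0.57 and 4.16, and miR-451 and miR-144 2.18 and 5.08. The last pair lay closer with identical tags alone, at 3.45 and 4.09. Between arms, miR-126-3p and miR-126-5p stood at -0.52 and 2.05. These differences within a pair do not depend on the scaling between libraries.

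**Figure D4:**
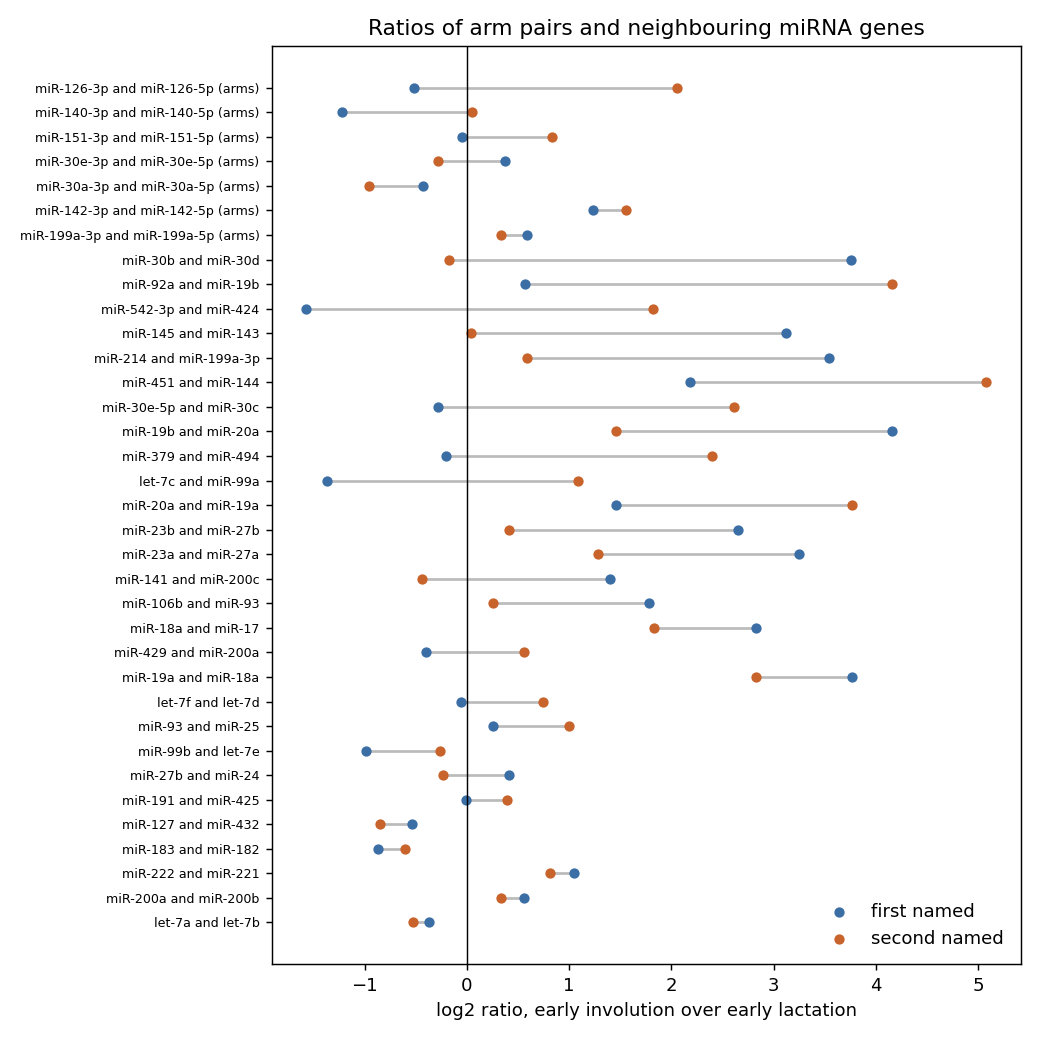
Log2 ratio of involution over lactation for both members of 35 pairs, opposite arms of a precursor (arms) or neighbouring genes; blue is the first-named member, orange the second, and the grey line joins them. Pairs such as miR-30b and miR-30d, at 3.76 and -0.17, are joined by long lines, and 17 of the 35 pairs are more than 2-fold apart.

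The ends of abundant miRNAs differed between the stages as well. Tags of miR-143 shorter than the panel sequence at the 3' end made up 48.8% in lactation (48.76 to 48.85%) and 66.8% in involution (66.77 to 66.89%). Those of miR-148a made up 1.03% and 5.27%, and those of let-7a 24.3% and 30.8%, whereas for miR-21 the share was 23.8% in lactation and 19.2% in involution. Over 82 miRNAs this share was higher in involution in 37, lower in 33 and had overlapping intervals in 12. Tags that lacked bases at the 5' end were a larger share in involution in 44 of the 82, a smaller one in 4 and overlapped in 34. For miR-143 the 5'-shortened share was 0.641% in lactation and 3.74% in involution, for let-7a 0.324% and 2.46%, and for miR-375, in the other direction, 5.48% and 1.96%.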

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

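Of the tests in this part, those on counting error within pairs, on assignment by the first 18 bases within pairs, on base composition across miRNAs and within pairs, on the number of miRNAs with a higher 5'-shortened share and on the trend with abundance, with and without miRNAs low in a library, were chosen after the result was seen, and the intervals for the pooled 5'-shortened share and for the share of miRNAs with more 3' shortening were brought into the verdicts after the values were seen; the stage of the gland and the library cannot be separated with 1 library each, so a biological difference between the stages stayed untested throughout.

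Some signals lay outside the assigned miRNAs and above what a count of 0 allows. In the filtering log of the involution library, 14.03% of high-quality reads had been removed as 5' adaptor contaminants, against 0.0505% in lactation. The most abundant tag without a 14-base match to the panel, GCGGGTGATGCGAACTGGAGTCTGAGT, had 6783 TPM in lactation and 1304 in involution. Tags over 30 nt, beyond the stated size range, numbered 37588 in lactation and 9942 in involution, or 0.208% and 0.135% of tags. Among tags of 36 to 44 nt, 4167 in lactation consisted of 2 panel miRNAs joined end to end, against 74 in involution, or 231 and 10.02 TPM.

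The first pattern is the difference in ratio between arms of a precursor and between neighbouring miRNA genes, by a median of 0.99 on the log2 scale. Counting error was too small, with intervals apart in 32 of 35 pairs, and assignment by the first 18 bases left the median difference at 0.995 times its value in 28 pairs, against tags lost at variable 3' ends there; the other 7, such as miR-30b and miR-30d, have no value under it. GC content as the whole cause was at odds with the pairs. Subtracting the median of each of 3 GC bins left their median difference at 1.54 times its value (bootstrap interval 0.835 to 1.87). Only 17 of the 35 pairs lay in different GC bins, so the others could not change under that step. Across 143 miRNAs, which are not independent replicates, Spearman's rho of GC content with the log2 ratio was -0.087 (-0.251 to 0.083), or -0.156 given level. A part played by GC content stays open, as the median log2 ratio was 1.51 up to 40% GC, 0.47 over 40 to 50% and 0.83 above, and the lower-GC member was the higher in 61.3% of the pairs that differed in GC. Processing or stability of single miRNAs that differs between the stages may account for it, and so may recovery of single miRNAs that differed between the library preparations for another reason.

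The second pattern is the larger share of 5'-shortened tags in involution. By count it did not rest on a few miRNAs: the share was higher beyond counting intervals in 44 of 82 miRNAs and lower in 4. That count was made a test after it had been seen. Without miR-143 the pooled share was 1.72% in lactation and 2.59% in involution, 1.51 times higher (bootstrap interval over miRNAs 1.14 to 2.64). This value met the limit set in advance against a few miRNAs, but its interval, asked for later, did not. Breakdown of RNA from both ends stays open: the 3'-shortened share was higher in involution in 37 of 82 miRNAs, or 45.1% (34.1 to 56.5%), and lower in 33; in advance 75% had been set as the least for that explanation and 50% as the most against it, so the value meets the latter but its interval, asked for later, does not. The pooled 3'-shortened share without miR-143 was 18.8% in lactation and 21.1% in involution. Reads removed as under 18 nt were 0.920% and 4.14% of high-quality reads. Both go with breakdown but are not specific to it. The pooled share also moves with the mix of miRNAs. In lactation 1.03% of miR-148a tags and 63.4% of miR-26a tags were 3'-shortened, and miR-148a was lower and miR-26a higher in involution. Reads removed for lack of an insert differed as well, at 0.945% and 7.73%. Differences in adaptor removal, since the logs differ so much at that step, and a difference between the stages remain possible and were not tested.

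The third pattern is the excess of miRNAs higher in involution when scaled to all tags. The most abundant miRNA, miR-143, did not set it, as the median log2 ratio was 0.83 without miR-143 in the totals. That outcome followed from its near equal share of all tags, 30.95% in lactation and 31.8% in involution. Other abundant miRNAs were not left out in this way. A trend with abundance was present, with rho of -0.45 between mean level and log2 ratio across the 143 miRNAs (bootstrap interval -0.57 to -0.31). The limit of 10 TPM in either library admits low miRNAs through the stage where they are high; among the 123 that reached it in both, rho was -0.35 (-0.50 to -0.18), and the median log2 ratio under 100 TPM was 1.07 instead of 1.82. Such a trend may come from a flatter distribution of miRNAs in the involuting gland or from library preparation, and these data do not separate them.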

How the results depend on the processing

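The alternatives by the first 18 bases, by tags of 18 to 30 nt and with the GC trend removed were chosen after seeing the data; the others were planned. No paired analysis was possible because each stage had 1 pooled library, and for the same reason no library could be left out. In the 11 alternatives with values per miRNA, none of the 35 miRNAs named by the rule and called was called in the other direction. The first 18 bases gave values for 31 of the 35. The scalings and the use of tags of 18 to 30 nt shift all ratios alike, the largest by -0.81 on the log2 scale. Such a shift cannot reverse a call, so only the assignment rules and the GC trend could have done so. With median-of-ratios and with TMM factors 5 of the 35 were no longer called, and with identical tags 2. The 2 other settings of the level filter and the thinning gave counts alone. Some list medians near 0 changed sign: with identical tags the epithelial median became 0.36, by the first 18 bases that of let-7 became 0.09, and with the GC trend removed those of the inflammation-induced list and the miR-424 cluster became -0.05 and -0.09. The count of miRNAs at least 2-fold higher, 64, ranged from 41 to 73, and that of miRNAs lower, 9, from 6 to 36. The count lower became 36 with median-of-ratios and 34 with TMM factors, which shift every ratio by 1 factor. The count higher became 41 when 100 TPM were required, with 105 miRNAs tested instead of 143. The share of tags assigned to miRNAs, 80.8% in lactation and 74.3% in involution, was 29.5% and 24.7% with identical tags alone, 81.7% and 75.3% with a shifted start allowed, 84.3% and 78.0% with 1 mismatch, and 80.8% and 74.4% with shared tags split. The 22 nt share was 11.1% and 11.97% of distinct sequences instead of tags. Thinning lactation to the depth of involution gave 64 higher and 9 lower, of which 63 and 9 were also called at full depth, so depth set few of the calls; miRNAs with few tags in lactation, such as miR-193a-3p, have wide intervals.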

Other observations

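The test in this part was chosen after the joined tags had been seen. Tags without a match to the panel differed in kind between the stages. A class of 24 to 32 nt with TGATG in the first 12 bases and CTGA in the last 8, motifs of C/D box small nucleolar RNAs, reached 12389 TPM in lactation and 2743 in involution, 4.52-fold lower (4.45 to 4.58). By contrast, AACAATGTAGGTAAGGGAAGTCGG had 208 TPM in lactation and 1075 in involution, 5.16 times higher (4.96 to 5.37); among its most abundant end variants the ratio ran from 3.47 with a further base at the start to 20.5 with a further base at the end. The tag TTAACATGTTGACAAGTCTAACTCTGAAG had 859 TPM in lactation and 2.57 in involution, and the form without its first base 791 and 47.5, so that the fold depends on the 5' end. These tags were picked for their abundance, and without a genome sequence their origin is not assigned.

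Among closely related miRNAs, 34 pairs differed by at most 2 bases. They were 0.76 apart in median on the log2 scale, against 1.504 for random pairs, and 8 of them were more than 2-fold apart. Many of these pairs were among let-7 members, which recur, so the pairs are not independent. Ratios also went with level, at a median log2 ratio of -0.05 from 1000 TPM up and 1.82 under 100 TPM. The comparison with random pairs therefore does not isolate likeness of sequence. The members miR-29a and miR-29c, which differ by 1 base, stood at 2.27 and 5.46.

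The joined tags of the lactation library had a makeup of their own. In 2223 of the 4167, or 53.3%, miR-22-3p was followed by miR-21, a combination found once in involution. As a share of positions in joined tags miR-22-3p took 26.9%, against 0.0126% of single miRNA tags, while miR-143 took 1.88% against 38.3%. Of the tags of 36 to 44 nt, 6.399% contained adaptor sequence in lactation and 70.7% in involution.

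The joined tags of lactation followed the involution levels beyond what the lactation levels explain. Across 130 groups of miRNAs, which are not independent replicates, the partial Spearman correlation of joined tags with the involution level given the lactation level was 0.367 (bootstrap interval 0.210 to 0.522), and 0.370 without miR-21 and miR-22-3p. With the lactation level given the involution level it was 0.039. Whether single tags of some miRNAs were under-counted in the lactation library cannot be told apart from other origins of the joined tags, because this correlation restates what was seen and tests no origin.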
